A study of Mus musculus with 12 samples.

How the data were processed

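RNA was sequenced from mature thymocytes of 4 groups with 3 libraries each: WT CD4 and WT CD8 cells of C57BL/6 mice, and Lz-Thpok CD4 and Mta2-DBTBLZ CD4 cells of retrogenic hosts. Per the labels' protocols, every sort took CD45.2-positive, TCRβ-high cells low in CD44, CD24 and CD69, and the retrogenic sorts also required Thy1.1 and the gate written intGFPlo. Libraries were made with SMARTer Ultra Low Input and Nextera XT reagents and sequenced as paired 75 bp reads with a target of 70 M pairs per sample, per the labels. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic, STAR, HTSeq, DESeq2 and the genome build mm10, without the role or order of each. The gene annotation and whether counting used strand are not given in the sources used here, and overlapping genes on opposite strands could then share reads.

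The authors deposited whole-number read counts per gene for each sample, not normalized, with 55353 genes per sample. Rows that name no gene were kept out of library sizes and tests. They held reads outside genes (4.86% to 9.55% of all rows' counts), ambiguous reads (5.18% to 6.23%) and reads aligned at several places (6.24% to 7.57%). The authors also deposited a table of their own comparisons with log2 fold changes and adjusted p-values, and 12 columns of per-sample values. Those 12 columns were not used, since 3 carry the name MTA2LzKK, which is not a sample label here. From that table only the authors' counts of passing genes and the log2 values of single genes are quoted. Its 28182 rows include 23 whose gene name had turned into a date.

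Groups and replicate numbers came from the sample labels. No pair of replicates was a repeated library, as every pair differed by more than counting noise in a chi-square test. The 4 comparisons used 1 edgeR 4.0.16 fit in R 4.3.3 of all 12 libraries, so that they share 1 estimate of the spread: TMM factors, filterByExpr on the groups (14668 genes kept of 30389 with any count), a robust quasi-likelihood fit and F test, no covariate, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. Fold changes are the first group minus the second, on the log2 scale, and CPM values use TMM-scaled library sizes. The SE of a fold change was derived from the test, as its absolute log2 value over the square root of the F statistic. For a group with 0 counts, folds use a floor of 3 counts over the group.

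A total of 24 gene lists with 510 symbols were fixed before the data were examined, and 508 symbols were found, 8 of them under another name. Each list with at least 3 tested genes was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 22 lists tested in a comparison. The erythroid and sex-linked lists each had 1 tested gene and were only described. An estimated correlation and fry served as alternatives. Named genes followed a rule fixed at the same time. It named Zbtb7b, Mta2, Cd4, Cd8a, Cd8b1, Runx3 and Thy1 always. It added up to 10 genes per direction with the largest fold change among called genes with a mean log2 CPM of at least 3 and no overlap of the groups' values, leaving out predicted genes, pseudogenes and receptor segments. Up to 4 called members per list followed, or 2 of the highest CPM where none was called. The overlap genes, the 8 called in both comparisons with WT CD4, are given in full. Of these, Gm43698, Ly6d and Slc43a1 fall outside that rule and were chosen after their values were seen.

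The lineage sets held genes called between WT CD4 and WT CD8 with an absolute log2 fold change of at least 1. The lineage index is the mean log2 CPM (prior count 2) of the CD4-enriched set minus that of the CD8-enriched set, scaled to the WT means, and was compared with an exact two-sided permutation test. Simulations of 30 draws gave the values that unchanged groups would show under independent genes with 1 spread per gene for all groups. They hold no variation shared across genes, so their ranges may be too narrow. The same rule chose more genes in simulated data, 997 in 1 data set, against 262 CD4-enriched and 286 CD8-enriched genes in the real data.

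Gene positions and exon lengths came from GENCODE M21 on mm10, which matched 120 of 122 named genes and may differ from the authors' annotation. The gene calls and camera were tested on counts simulated from the real means and library sizes with known changes. Changed genes were drawn among those of at least 8 CPM in the second group. Each gene had 1 spread for all groups, although real Mta2-DBTBLZ replicates spread more than the others, so shares called for that group may be too high. In 14038 genes simulated for Mta2-DBTBLZ against Lz-Thpok, 45% of genes changed 2-fold and 94% of those changed 4-fold were called. For Lz-Thpok against WT CD4 the shares were 51% and 97% over 14011 genes, for Mta2-DBTBLZ against WT CD4 43% and 97% over 14063 genes, and for WT CD4 against WT CD8 61% and 96% over 13971 genes. Beside these changed genes, 4, 8, 6 and 7 unchanged genes were called in the same order. In Lz-Thpok libraries simulated as 20% WT CD8 and 80% WT CD4, the median share of the WT CD8 level came out at 19.6% over 86 abundant genes. The lineage index was 0.691 over 997 genes, against 0.731 from the means put in, a shortfall in the direction that the choice of genes gives. Of 100 genes changed 4-fold alike in both retrogenic groups, 95 were called in both, among 14048 tested, and no other gene was. In 30 simulated draws with no change from WT CD4, edgeR called at most 1 gene for Lz-Thpok and at most 2 for Mta2-DBTBLZ against WT CD4.

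Alternatives fixed before the data were examined were other scalings (median-ratio and upper-quartile), DESeq2 1.42.0, limma voom, no low-count filter, a filter of 5 CPM in 3 libraries, only the 6 compared libraries, the replicate number as a block, each replicate left out, other fold thresholds of the sets, and another prior count. Those added later were quality weights per library in limma voom, the share of reads outside genes or the mitochondrial share as a covariate, removal of each library's trend with exon length, and the leave-outs of the overlap.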

Results

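RNA sequencing measured gene expression in mature mouse thymocytes sorted by flow cytometry into 4 groups of 3 libraries. The WT CD4 and WT CD8 groups held mature CD4 and CD8 cells of C57BL/6 mice. The other 2 groups were retrogenic CD4 cells: marrow lacking Thpok in T cells (a Cd4-Cre driver with floxed Thpok) had received a retroviral construct and was transplanted into irradiated hosts. The sample labels name the constructs Lz-Thpok and Mta2-DBTBLZ, whereas the series text names them DBTBLZ and Mta2-DBTBLZ. Lz-Thpok was taken as the group the text calls DBTBLZ. Neither source says that they are 1 construct, and neither spells out the abbreviations. Thpok is the product of Zbtb7b, the transcription factor that commits thymocytes to the CD4 lineage, and Mta2 is a subunit of the NuRD chromatin-remodeling complex. Each library held between 22578348 and 30314528 reads counted in genes, so a single library's floor of 3 counts lay between 0.0990 and 0.133 CPM (read counts scaled to the library's total). Floors cover counting error only. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries.

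Zbtb7b (chromosome 3, 89377644 to 89394776, mm10) checked the labels first. WT CD4 libraries held 69.6 ± 9.54 CPM (SD, n = 3), and all 3 WT CD8 libraries held 0 counts, which placed WT CD4 at least 1911-fold higher than the floor of 3 counts over the WT CD8 group. Lz-Thpok CD4 libraries held 33.1 ± 4.41 CPM (SD, n = 3) and Mta2-DBTBLZ CD4 libraries 6.81 ± 3.53 CPM (SD, n = 3), ranging from 2.80 to 9.42 CPM. Gene-level counts cannot separate construct reads from reads of the floxed gene, nor show which part of Zbtb7b a construct holds, so these levels check only that CD4 and CD8 libraries were labelled apart. Mta2 (chromosome 19, 8941875 to 8952303) read 454 ± 29.0 CPM in WT CD4, 509 ± 24.9 in WT CD8, 497 ± 43.5 in Lz-Thpok CD4 and 507 ± 87.4 in Mta2-DBTBLZ CD4 (SD, n = 3 each). Gene-level counts do not separate construct reads from endogenous Mta2 reads either, so Mta2 did not check the construct label. Thy1, whose Thy1.1 form marks the retrogenic sort, read 56.5 CPM in WT CD4, 81.5 in WT CD8, 87.7 in Lz-Thpok CD4 and 79.1 in Mta2-DBTBLZ CD4, with no call in the comparison of WT CD4 with WT CD8 (edgeR adjusted p = 0.305). Zbtb7b has exons that overlap Gm15417 on the opposite strand. The other lineage genes named throughout are Cd4 (chromosome 6, 124864692 to 124888221), Cd8a (chromosome 6, 71373427 to 71379173), Cd8b1 (chromosome 6, 71322788 to 71337494), Nkg7 (chromosome 7, 43437073 to 43438249) and Runx3 (chromosome 4, 135120652 to 135177990).

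**Figure D1:**
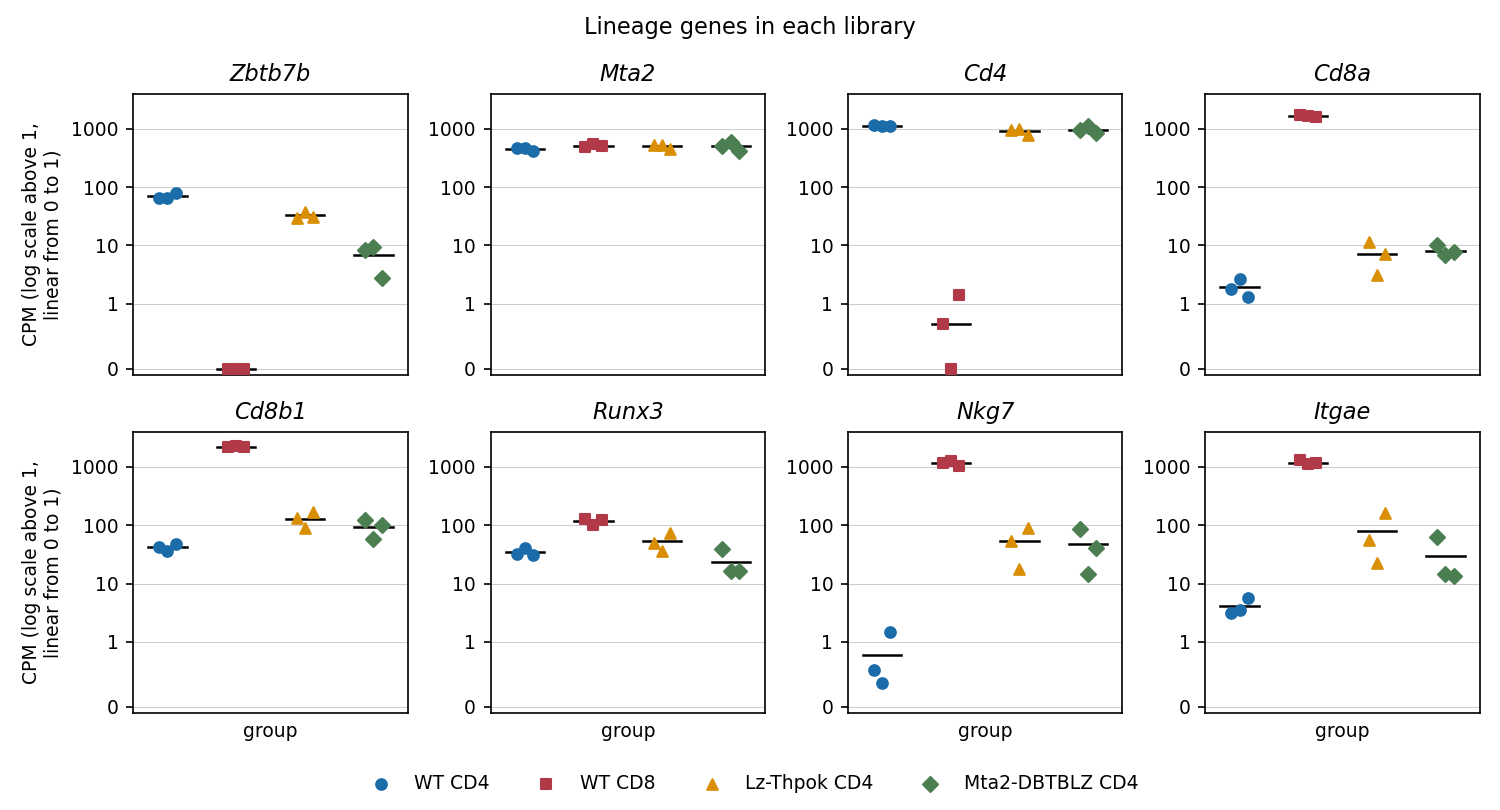
CPM of 8 genes (vertical axis, logarithmic above 1 CPM and linear from 0 to 1) in the 4 groups (horizontal axis), with 1 point per library, 3 per group, and a bar at the group mean. Retrogenic CD4 libraries keep Cd4 near the WT CD4 level, hold Cd8a between 3.08 and 11.5 CPM against 1625 CPM in WT CD8, and differ in Zbtb7b (33.1 against 6.81 CPM).

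The comparison of WT CD4 with WT CD8 cells asked what separates the normal mature lineages. Coreceptor genes parted as the sort required: Cd4 was higher in WT CD4 (1121 ± 24.5 against 0.694 ± 0.699 CPM, SD, n = 3), while Cd8a (1.91 ± 0.674 against 1625 ± 66.0 CPM) and Cd8b1 (42.0 ± 5.76 against 2196 ± 66.6 CPM) were higher in WT CD8. WT CD4 cells had more Cd40lg, the CD40 ligand of T cell help (121 ± 5.61 against 1.07 ± 0.708 CPM), more St8sia6, a sialyltransferase (192 ± 8.94 against 2.95 ± 1.72 CPM). They also had more Tnfrsf4, which encodes the costimulatory receptor OX40 (142 ± 23.1 against 3.87 ± 2.13 CPM). WT CD8 cells had more Nkg7, a cytotoxic granule protein (1137 ± 114 against 0.805 ± 0.588 CPM), Itgae, the integrin chain CD103 (1179 ± 105 against 4.07 ± 1.38 CPM), and Cxcr6, a chemokine receptor (355 ± 112 against 4.66 ± 1.28 CPM). Runx3, the transcription factor of the CD8 lineage, read 117 ± 14.1 CPM in WT CD8 and 34.8 ± 5.57 CPM in WT CD4 (log2 fold change -1.75, SE 0.34, edgeR adjusted p = 0.00875), a call lost without WT CD4 replicate 3 (edgeR adjusted p = 0.0506). Other genes of large change were Ptgir, Myo10, Foxp3, Pdlim4, L1cam and Tbc1d4, higher in WT CD4, and Adgrg5, Baiap3, Klrd1 and Cd160, higher in WT CD8.

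Of the 20 CD4 lineage and helper genes tested, 12 were higher in WT CD4 and 8 did not pass (14 higher when adjusted over the list alone, camera adjusted p = 6.05e-36). Of 29 CD8 lineage and cytotoxic genes, 14 were lower and 2 higher in WT CD4, and 13 did not pass (16 lower and 2 higher adjusted over the list alone, camera adjusted p = 3.63e-28). The 2 exceptions included Ly6c1, at 32.3 ± 12.1 CPM in WT CD4 and 0.242 ± 0.0804 CPM in WT CD8, whereas its close paralog Ly6c2 was higher in WT CD8 (82.2 ± 13.4 against 3.74 ± 1.76 CPM). Among 29 transcription factors of lineage choice, 11 were higher and 3 lower in WT CD4 (14 and 4 adjusted over the list alone, camera adjusted p = 1.84e-07), including Prdm1 (log2 fold change 3.08) and Runx1 (1.86). Regulatory T cell genes were higher in WT CD4, with 6 of 16 called (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.40e-11), among them Foxp3, the regulatory T cell transcription factor (42.9 ± 12.2 against 2.69 ± 1.49 CPM), Il2ra and Itih5. The Foxp3 call was lost without any one of WT CD4 replicates 1 and 3 or WT CD8 replicates 1, 2 and 3 (edgeR adjusted p for Foxp3 between 0.0556 and 0.116).

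Proliferation genes were lower in WT CD4 cells than in WT CD8 cells: 13 of 33 were called and none of the 33 was higher (24 lower adjusted over the list alone; median log2 fold change -1.09, camera adjusted p = 2.20e-25). Replication-licensing genes were among them, such as Mcm5 (85.6 ± 5.41 against 291 ± 17.3 CPM) and Mcm6 (176 ± 12.8 against 551 ± 31.1 CPM). Invariant NKT and innate-like markers were also lower in WT CD4, with 6 of 15 called (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.87e-14). So were NK cell markers, with 2 of 6 called, Klrd1 and Prf1 (3 adjusted over the list alone, camera adjusted p = 3.16e-05). The called genes of both lists, such as Nkg7, Cd160, Ccr9, Klrd1 and Prf1 (the perforin gene), are also used by CD8 T cells. NK-specific Ncr1 was at or below 0.177 CPM in every library. B cell markers were lower in WT CD4, with 3 of 5 called (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 8.78e-06): Cd79b, Ighd and Ighm. These 8 calls held with an estimated correlation between genes, with camera adjusted p between 4.03e-05 and 0.0371. Of 14 NuRD subunits, Chd3 was higher in WT CD4 (238 ± 34.1 against 110 ± 27.2 CPM), and Mta3, Gatad2a and Rbbp7 were lower (1 higher and 4 lower adjusted over the list alone), with no call for the list (camera adjusted p = 0.0548). The Chd3 call was lost without any one of WT CD4 replicates 1, 2 and 3 or WT CD8 replicates 1 and 2 (edgeR adjusted p between 0.0842 and 0.197). The Rbbp7 call was lost without WT CD4 replicate 3 (edgeR adjusted p = 0.0771) or WT CD8 replicate 2 (edgeR adjusted p = 0.0597), and the Ighm call without WT CD4 replicate 1 or 3 or WT CD8 replicate 2 (edgeR adjusted p up to 0.0878).

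Smaller shifts marked 4 more lists, each lost with an estimated correlation. TCR signal response genes were higher in WT CD4, with 6 called higher and 1 lower of 25 (7 and 3 adjusted over the list alone, camera adjusted p = 0.000398, and adjusted p = 0.0607 with an estimated correlation), including Nr4a1 (218 ± 6.42 against 82.0 ± 13.1 CPM) and Dusp5. Late maturation and egress genes (6 higher and 2 lower of 24; 7 and 4 adjusted over the list alone) had camera adjusted p = 0.0294, and adjusted p = 0.346 with an estimated correlation, and were not called without WT CD8 replicate 1 or 3 (camera adjusted p = 0.114 and 0.137). Type I interferon response genes (2 higher of 42, Ly6a and Slfn5; 10 higher and 2 lower adjusted over the list alone) had camera adjusted p = 0.00945, and adjusted p = 0.346 with an estimated correlation. Oxidative phosphorylation genes, with none of 37 called and none adjusted over the list alone, had a median log2 fold change of -0.17 (camera adjusted p = 0.0280, and adjusted p = 0.689 with an estimated correlation), and were not called without WT CD4 replicate 2 or WT CD8 replicate 1 (camera adjusted p = 0.143 and 0.128).

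Over all 14668 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 816 genes between WT CD4 and WT CD8, 366 higher and 450 lower in WT CD4. Of all tested genes, 32.7% had CPM values that did not overlap between the groups, against 10% by chance. Calls fell to between 447 and 488 without any one of WT CD4 replicate 1, 2 or 3 or WT CD8 replicate 1 or 2, and numbered 1542 with DESeq2. Values of Baiap3, Ccr9, Cd160, Dusp5, Foxp3, L1cam, Slfn5, St8sia6, Rbbp7 and Runx1 are uncertain because their exons overlap those of other genes. The same holds for Bcl6 and Il21, named further below.

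The comparison of Lz-Thpok CD4 with WT CD4 cells asked how CD4 cells that rely on that construct differ from normal ones. These cells kept Cd4 (914 ± 114 against 1121 ± 24.5 CPM, SD, n = 3; edgeR adjusted p = 1) and had higher levels of several CD8-lineage genes. Nkg7 was higher (53.5 ± 36.0 against 0.805 ± 0.588 CPM; log2 fold change 6.04, SE 0.81, edgeR adjusted p = 0.0184). Also higher were Adgrg5, an adhesion G protein-coupled receptor (43.2 ± 35.2 against 3.11 ± 0.975 CPM) and Cd8b1 (129 ± 37.9 against 42.0 ± 5.76 CPM). Ly6c1, which was higher in WT CD4 than in WT CD8, rose further (263 ± 141 against 32.3 ± 12.1 CPM). Dntt, the terminal transferase of developing lymphocytes, was 90.4 ± 31.3 against 21.6 ± 5.18 CPM and also higher, together with Cxxc5, Usp11 (a deubiquitinase) and Anxa2. Ckb, a creatine kinase (38.8 ± 13.2 against 115 ± 4.66 CPM), Rgmb, a coreceptor of the BMP pathway (15.8 ± 0.805 against 46.4 ± 5.25 CPM), and Tmem64 (136 ± 16.5 against 277 ± 5.43 CPM) were lower. Zbtb7b did not pass (log2 fold change -1.07, SE 0.35, edgeR adjusted p = 0.481), though it did in the fit to the 6 compared libraries alone (edgeR adjusted p = 0.0366). Neither did Cd8a (7.20 ± 4.22 against 1.91 ± 0.674 CPM, edgeR adjusted p = 0.105) pass, nor Runx3 (53.2 ± 18.3 against 34.8 ± 5.57 CPM, edgeR adjusted p = 0.877). Values of Cd8a did not overlap between the groups (lowest 3.08 against highest 2.63 CPM), and Cd8a passed with DESeq2 (adjusted p = 0.000167) and without Lz-Thpok replicate 2 (edgeR adjusted p = 0.0184).

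Of 29 CD8 lineage and cytotoxic genes, 3 rose (Nkg7, Ly6c1 and Cd8b1) and 26 did not pass (10 higher adjusted over the list alone; median log2 fold change 0.57, camera adjusted p = 2.61e-14), while 24 of the 29 had a positive fold change. Of these 3, Ly6c1 was higher in WT CD4 than in WT CD8 (32.3 against 0.242 CPM), so its rise was no shift toward the WT CD8 level. No member of the 20 CD4 lineage and helper genes passed (3 lower adjusted over the list alone), and it ranked lower as a set (median -0.35, camera adjusted p = 9.60e-06). Invariant NKT and innate-like markers ranked higher, with Nkg7 called of 15 (4 adjusted over the list alone; median 1.22, camera adjusted p = 3.52e-07). NK cell markers ranked higher with none of 6 called (3 adjusted over the list alone, camera adjusted p = 0.000252), Prf1 being at 76.0 ± 25.5 against 21.1 ± 4.46 CPM. Immature and double-positive thymocyte genes ranked higher with 1 of 27 called, Dntt (4 adjusted over the list alone; median 0.49, camera adjusted p = 5.84e-07). B cell markers ranked higher with none of 5 called (2 adjusted over the list alone, camera adjusted p = 0.000256), Ighm being at 652 ± 217 against 309.9 ± 48.02 CPM. These 6 calls held with an estimated correlation (camera adjusted p between 0.0305 and 0.0400).

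Further lists ranked apart without that support and with no member called over all genes. Gamma delta T cell markers ranked higher (median 0.74; 2 of 8 higher adjusted over the list alone, camera adjusted p = 0.00366, and adjusted p = 0.0954 with an estimated correlation). Trdc, the delta chain constant region, read 35.7 ± 15.4 against 9.16 ± 1.38 CPM. Type I interferon response genes ranked lower (median -0.27; 5 lower and 1 higher of 42 adjusted over the list alone, camera adjusted p = 6.58e-07, and adjusted p = 0.0954 with an estimated correlation). Dissociation and heat stress genes ranked higher (median 0.27; none of 20 adjusted over the list alone, camera adjusted p = 0.000600, and adjusted p = 0.217 with an estimated correlation). Regulatory T cell genes ranked lower (median -0.30; 2 of 16 lower adjusted over the list alone, camera adjusted p = 0.000256). So did proliferation genes (median -0.30; none of 33 adjusted over the list alone, camera adjusted p = 5.59e-05), both with adjusted p = 0.217 with an estimated correlation. Mitochondrially encoded genes (median -0.34, camera adjusted p = 0.0371) and oxidative phosphorylation genes (median -0.14, camera adjusted p = 0.00109) ranked lower, with none adjusted over either list alone and adjusted p = 0.616 with an estimated correlation for each. Mitochondrial genes took 0.715%, 0.485% and 1.31% of the counts in Lz-Thpok replicates 1, 2 and 3, against 0.979% to 1.17% in WT CD4. Without Lz-Thpok replicate 2 neither list was called (camera adjusted p = 0.974 and 0.382), and the mitochondrially encoded list also lost its call without Lz-Thpok replicate 1 or WT CD4 replicate 2 or 3 (camera adjusted p up to 0.139).

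In total edgeR called 16 genes between Lz-Thpok CD4 and WT CD4, 12 higher and 4 lower, and 950 passed an unadjusted p of 0.05. The balance of directions depended on the fit: limma voom called 0 higher and 3 lower, and edgeR on the 6 compared libraries alone 26 higher and 27 lower. Non-overlapping CPM values occurred in 15.5% of tested genes, against 10% by chance. Leaving out WT CD4 replicate 1, 2 or 3 left 2, 5 and 0 calls (edgeR, the last with 773 genes at an unadjusted p under 0.05), and leaving out Lz-Thpok replicate 1 left 3. DESeq2 called 226, and each of the 11 called genes named here lost its call without at least 1 library. Cxxc5 and Anxa2 share exon positions with other genes and Ly6c1 has a close paralog, so their values are uncertain.

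The comparison of Mta2-DBTBLZ CD4 with WT CD4 cells asked the same of the Mta2 construct. Zbtb7b was lower (6.81 ± 3.53 against 69.6 ± 9.54 CPM, SD, n = 3; log2 fold change -3.35, SE 0.39, edgeR adjusted p = 0.0242), and the construct and the floxed gene contribute to this count in unknown parts. Nkg7 was higher (46.7 ± 35.5 against 0.805 ± 0.588 CPM; log2 fold change 5.84, SE 0.80, edgeR adjusted p = 0.0242). Other higher genes were Matk, a tyrosine kinase (69.6 ± 19.2 against 20.5 ± 1.13 CPM), Icam1, an adhesion molecule (77.9 ± 19.1 against 32.5 ± 3.46 CPM), Ighm (888 ± 276 against 309.9 ± 48.02 CPM), Slc28a2b, Agpat4, Ptprn, Usp11, Rundc3a, Cuedc2 and Anxa2. Lower genes were Top2a, the topoisomerase of dividing cells (14.4 ± 8.53 against 74.0 ± 19.2 CPM), Oas2, an antiviral oligoadenylate synthetase (20.2 ± 2.95 against 78.6 ± 21.8 CPM), Tnfrsf4 (39.9 ± 13.4 against 142 ± 23.1 CPM), Ckb (35.6 ± 3.31 against 115 ± 4.66 CPM), Cd6, Scrn3, Slfn9, Mpzl3, Parp12 and Tmem64. Cd4 (964 ± 139 CPM; edgeR adjusted p = 0.843), Cd8a (8.21 ± 1.66 CPM; edgeR adjusted p = 0.0519), Cd8b1 (93.7 ± 32.8 CPM; edgeR adjusted p = 0.106) and Runx3 (23.8 ± 12.9 CPM; edgeR adjusted p = 0.492) did not pass. Values of Cd8a did not overlap between the groups (lowest 6.80 against highest 2.63 CPM). With DESeq2 Cd8a (adjusted p = 1.55e-05) and Cd8b1 (adjusted p = 0.00324) passed, as both did without Mta2-DBTBLZ replicate 1 (edgeR adjusted p = 0.0261 and 0.0498).

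Proliferation genes ranked lower, with Top2a called of 33 (19 lower adjusted over the list alone; median log2 fold change -0.97, camera adjusted p = 9.25e-15, and adjusted p = 0.139 with an estimated correlation). Regulatory T cell genes ranked lower, with Tnfrsf4 called of 16 (7 adjusted over the list alone; median -0.96, camera adjusted p = 1.68e-06, and adjusted p = 0.148 with an estimated correlation). The fall was unequal: their mean log2 CPM was 4.497, 2.775 and 3.883 in Mta2-DBTBLZ replicates 1, 2 and 3, against 4.755 to 5.219 in WT CD4. CD4 lineage and helper genes ranked lower with 3 of 20 called, Zbtb7b, Tnfrsf4 and Cd6 (4 adjusted over the list alone, camera adjusted p = 0.000289, and adjusted p = 0.139 with an estimated correlation). Zbtb7b is the floxed gene of this marrow, so the design bears on its fall, and the list was not tested without it. CD8 lineage and cytotoxic genes ranked higher with Nkg7 called of 29 (9 adjusted over the list alone; median 0.83, camera adjusted p = 2.45e-06, and adjusted p = 0.152 with an estimated correlation). Their mean log2 fold change was smaller, 0.487, against 0.947 in Lz-Thpok. Their mean log2 CPM was 2.815, 1.927 and 2.188 in Mta2-DBTBLZ replicates 1, 2 and 3, against 1.375 to 1.9 in WT CD4. Type I interferon response genes ranked lower with 2 of 42 called, Oas2 and Slfn8 (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.000115, and adjusted p = 0.200 with an estimated correlation). Late maturation and egress genes ranked higher with none of 24 called (1 adjusted over the list alone; median 0.29, camera adjusted p = 0.000289, and adjusted p = 0.170 with an estimated correlation). So did dissociation and heat stress genes (none of 20 called, none adjusted over the list alone, camera adjusted p = 0.00250, and adjusted p = 0.270 with an estimated correlation). The 3 Mta2-DBTBLZ libraries differed here: the late maturation genes summed to 25750, 31970 and 35560 CPM in replicates 1, 2 and 3, against 24910 to 26090 in WT CD4, and mitochondrial genes took 1.14%, 0.480% and 0.638% of the counts, against 0.979% to 1.17% in WT CD4. Replicate 3 also stood apart in a trend with exon length (Spearman correlation -0.522, against 0.180 to 0.337 in WT CD4). The interferon list was not called without Mta2-DBTBLZ replicate 1 (camera adjusted p = 0.127).

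Among markers of other cell types, innate-like markers ranked higher, with Nkg7 called of 15 (1 adjusted over the list alone, camera adjusted p = 0.0420, and adjusted p = 0.259 with an estimated correlation). NK cell markers ranked higher with none of 6 called (2 adjusted over the list alone, camera adjusted p = 0.0152), and B cell markers with 1 of 5 called, Ighm (2 adjusted over the list alone, camera adjusted p = 0.00675), each with adjusted p = 0.148 with an estimated correlation. Without Mta2-DBTBLZ replicate 1 the innate-like (camera adjusted p = 0.433) and NK cell markers (camera adjusted p = 0.188) were not called, nor the innate-like markers without WT CD4 replicate 1 or 2 (camera adjusted p = 0.0592 and 0.0874).

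In total edgeR called 54 genes between Mta2-DBTBLZ CD4 and WT CD4, 34 higher and 20 lower, with non-overlapping CPM values in 16.9% of tested genes against 10% by chance. Here too the balance of directions depended on the fit: limma voom called 11 higher and 16 lower, and edgeR with the exon-length trend removed 19 and 19. Without WT CD4 replicate 1, 2 or 3 the calls numbered 2, 1 and 0 (edgeR, the last with 1143 genes at an unadjusted p under 0.05). Without Mta2-DBTBLZ replicate 1 they numbered 1173, 456 higher and 717 lower, without replicate 2 they numbered 1, and without replicate 3 they numbered 4. The edgeR fit to the 6 compared libraries alone called 0, with 1186 genes at an unadjusted p under 0.05, and DESeq2 called 406. The Zbtb7b call ended without any one WT CD4 library or without Mta2-DBTBLZ replicate 2 (edgeR adjusted p between 0.0659 and 0.122). Anxa2, Cuedc2, Icam1, Mpzl3, Ptprn, Scrn3 and Top2a share exon positions with other genes, and Slc28a2b, Slfn8 and Slfn9 have close paralogs, so their values are uncertain.

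Both retrogenic groups were compared with the same WT CD4 libraries, and 8 genes were called in the same direction in both. Anxa2, Gm43698, Ly6d, Nkg7, Slc43a1 and Usp11 were higher, and Ckb and Tmem64 lower. Independent lists would share 0.0278 higher and 0.00545 lower genes. Simulated unchanged groups against the same WT CD4 libraries shared 0 genes, but they called at most 1 gene for Lz-Thpok and 2 for Mta2-DBTBLZ. A shared count near 0 was thus fixed in advance there and is no measure for the 8. The covariance of the log2 fold changes over 8620 genes was 0.0814, against 0.0356 in the simulation, a difference of 0.0458 (correlation 0.653 against 0.496, across genes, which are not independent replicates). Without WT CD4 replicate 1, 2 or 3 the shared genes numbered 1, 1 and 0, and without Lz-Thpok replicate 1 they numbered 2. Without Mta2-DBTBLZ replicate 1, 2 or 3 they numbered 41, 1 and 2. With 3 WT CD4 libraries no split into parts of at least 2 is possible, so some of the 8 shared genes may come from the shared controls. In the authors' deposited table, 224 genes passed an adjusted p of 0.05 for WT CD4 minus ThpokCD4 and 394 for WT CD4 minus MTA2LzKKCD4, the table's own names. Its Zbtb7b log2 fold changes, 1.08 and 3.36 in that order, were close to those given above for Lz-Thpok and Mta2-DBTBLZ, with the sign turned. MTA2LzKKCD4 thus most likely stands for Mta2-DBTBLZ CD4, although no label says so.

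The comparison of Mta2-DBTBLZ CD4 with Lz-Thpok CD4 cells asked how cells with these constructs differ when transplantation, transduction and sort are alike. The labels do not say that the constructs differ only by Mta2. Zbtb7b was 6.81 ± 3.53 CPM in Mta2-DBTBLZ and 33.1 ± 4.41 CPM in Lz-Thpok libraries (SD, n = 3), with no overlap between the groups and no call (log2 fold change -2.28, SE 0.37, edgeR adjusted p = 0.392). It passed with DESeq2 (adjusted p = 5.20e-06) and without Mta2-DBTBLZ replicate 1 (edgeR adjusted p = 0.0449). Mta2 differed by a log2 fold change of 0.03 (SE 0.14, edgeR adjusted p = 0.970), Cd4 by 0.08 (SE 0.41, edgeR adjusted p = 0.970), Cd8a by 0.18 (SE 0.36, edgeR adjusted p = 0.903) and Cd8b1 by -0.46 (SE 0.26, edgeR adjusted p = 0.716). Runx3 read 23.8 ± 12.9 against 53.2 ± 18.3 CPM (log2 fold change -1.16, SE 0.33, edgeR adjusted p = 0.546). Ccr9, a gut-homing chemokine receptor, read 76.7 ± 57.6 against 240 ± 114 CPM (log2 fold change -1.64, SE 0.48, edgeR adjusted p = 0.555). Without Mta2-DBTBLZ replicate 1, Runx3 (edgeR adjusted p = 0.0301) and Ccr9 (edgeR adjusted p = 0.0340) passed. Ccr9 shares exon positions with other genes, so its values are uncertain.

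No gene passed edgeR's quasi-likelihood test (lowest adjusted p = 0.392), while 1002 genes had an unadjusted p under 0.05 and 8.98% had non-overlapping CPM values, against 10% by chance. DESeq2 called 91 genes (29 higher and 62 lower in Mta2-DBTBLZ), limma voom 0, and the edgeR fit without a low-count filter 5. In the authors' deposited table, 72 genes passed an adjusted p of 0.05 for ThpokCD4 minus MTA2LzKKCD4, 50 higher and 22 lower in ThpokCD4, and Zbtb7b had a log2 fold change of 2.28. Without Mta2-DBTBLZ replicate 1 edgeR called 109 genes, 15 higher and 94 lower. That fit, also used for the single genes above, rested on Mta2-DBTBLZ replicates 2 and 3. Their mitochondrial shares were 0.480% and 0.638%, against 1.14% in replicate 1, so its calls cannot be told apart from library quality. Replicates of Mta2-DBTBLZ spread most: the median SD of log2 CPM over 8620 genes was 0.324, against 0.207 in Lz-Thpok, 0.186 in WT CD8 and 0.146 in WT CD4.

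Between the retrogenic groups 7 lists ranked apart, none with an estimated correlation. Proliferation genes ranked lower in Mta2-DBTBLZ (median log2 fold change -0.50; 4 of 33 lower adjusted over the list alone, camera adjusted p = 1.34e-07), with 28 of the 33 negative and Mcm4 at 144 ± 23.2 against 178 ± 9.12 CPM. Also lower were regulatory T cell genes (median -0.38), innate-like markers (median -0.38) and immature and double-positive thymocyte genes (median -0.21), each with camera adjusted p = 0.0278, and transcription factors of lineage choice (median -0.07, camera adjusted p = 0.0413). Adjusted over each list alone, 0 of 16, 0 of 15, 4 of 27 and 1 of 29 genes were lower, in that order. Late maturation and egress genes ranked higher (median 0.19; none of 24 adjusted over the list alone, camera adjusted p = 0.0278). With an estimated correlation these 6 lists had adjusted p = 0.619. Oxidative phosphorylation genes ranked higher, with 36 of 37 positive (median 0.19; none adjusted over the list alone, camera adjusted p = 1.20e-05, and adjusted p = 0.655 with an estimated correlation). Beside these shifts, Mta2-DBTBLZ replicate 3 stood apart from the other libraries in a trend with exon length: its genes in the shortest 5th of exon lengths lay 0.329 above, and those in the longest 5th 0.463 below, the mean of all libraries on the log2 scale. Lists called numbered 2 without Lz-Thpok replicate 1, and 3 and 4 without Mta2-DBTBLZ replicates 2 and 3.

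**Figure D2:**
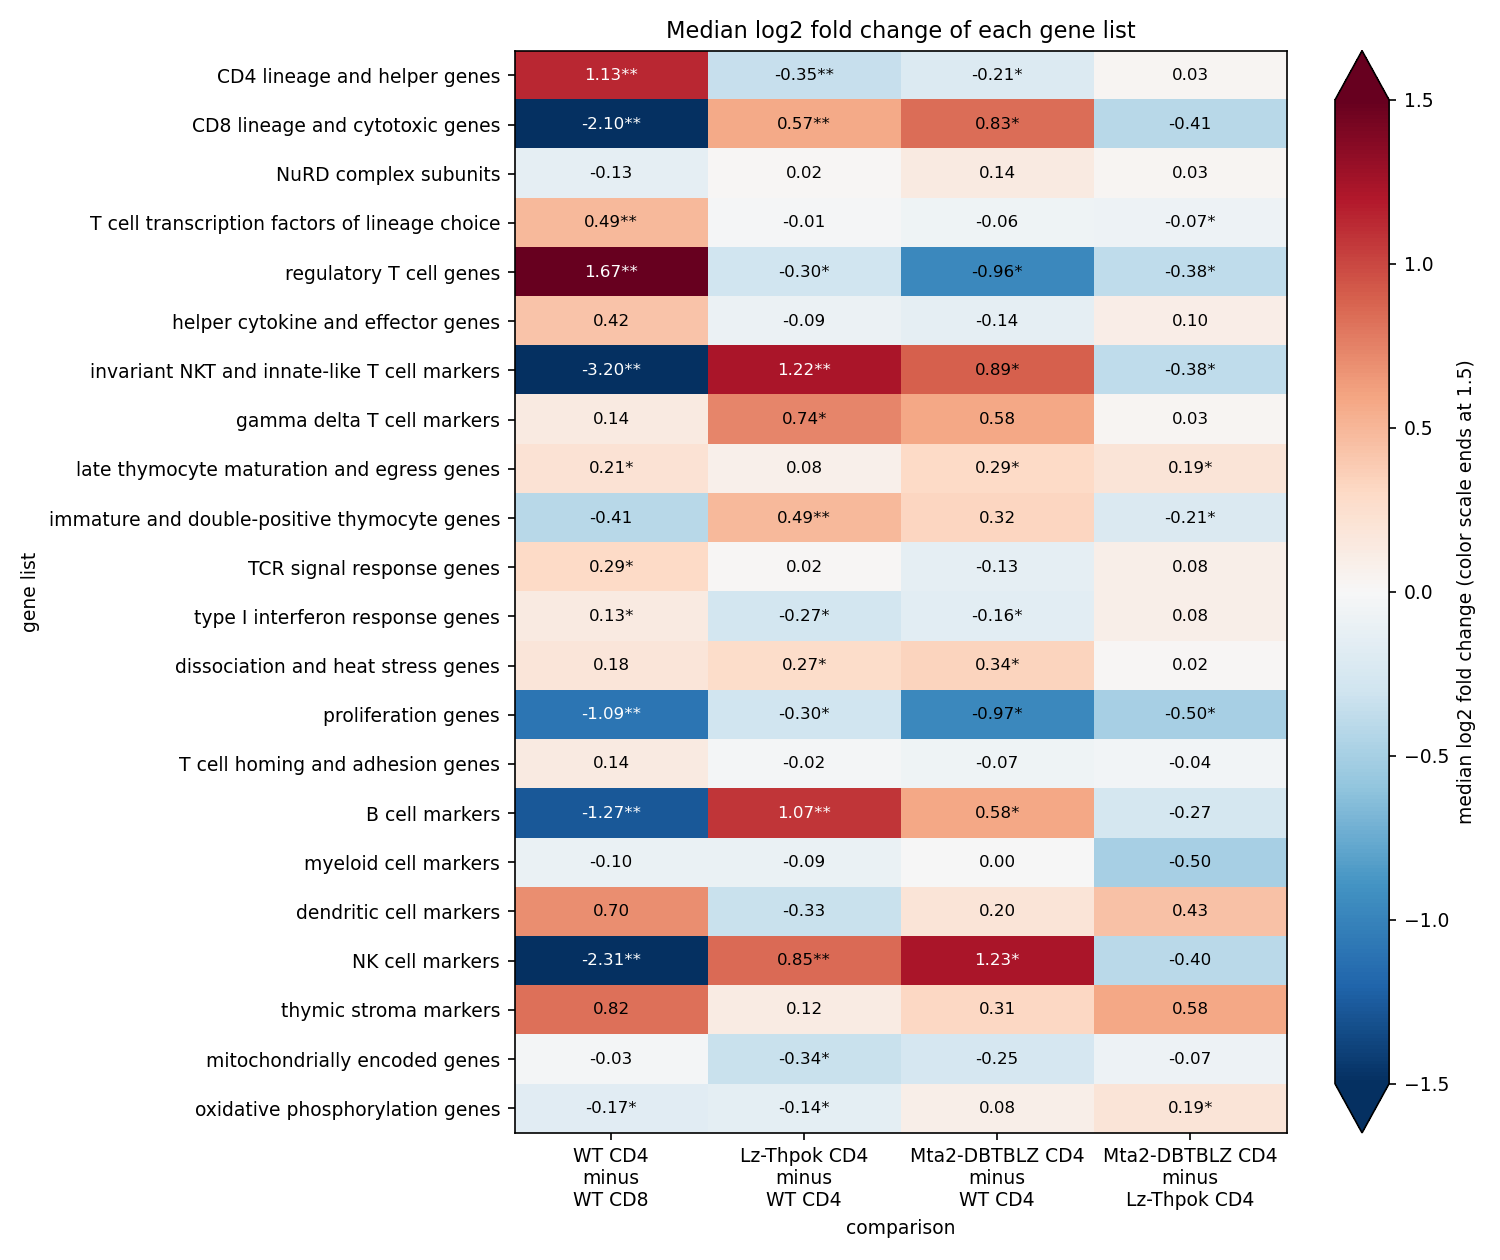
Median log2 fold change of 22 gene lists (vertical axis) in the 4 comparisons (horizontal axis), by color and number. One asterisk marks a camera adjusted p under 0.05 and a pair of asterisks a call that also holds with an estimated correlation. CD8 lineage and cytotoxic genes have medians of -2.10, 0.57, 0.83 and -0.41 from left to right. Their means against WT CD4 order the groups otherwise, with 0.947 in Lz-Thpok and 0.487 in Mta2-DBTBLZ. Only the columns of WT CD4 minus WT CD8 and Lz-Thpok minus WT CD4 hold pairs of asterisks.

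To place the retrogenic cells between the normal lineages, the genes called at a fold of at least 2 between WT CD4 and WT CD8 formed a set of 262 CD4-enriched and a set of 286 CD8-enriched genes. CD8-enriched genes had a median log2 fold change over WT CD4 of 0.53 in Lz-Thpok CD4 (228 of 286 positive, 10 called, camera adjusted p = 3.39e-39) and 0.39 in Mta2-DBTBLZ CD4 (19 called, camera adjusted p = 1.28e-16). CD4-enriched genes had medians of -0.31 (camera adjusted p = 1.13e-12) and -0.34 (camera adjusted p = 1.44e-08). All 4 calls held with an estimated correlation (camera adjusted p up to 0.00726). These sets were chosen on the WT CD4 libraries that also serve as controls, and unchanged groups simulated against them had medians of 0.113 (0.0797 to 0.142) for CD8-enriched and -0.157 (-0.198 to -0.128) for CD4-enriched genes. With each WT CD4 library in turn kept out of choosing the CD8-enriched set and used as the control, the median log2 difference was 0.485, 0.440 and 0.456 for Lz-Thpok and 0.340, 0.232 and 0.368 for Mta2-DBTBLZ. The median CD8-enriched gene lay at 12.1% of the way from its WT CD4 to its WT CD8 level in Lz-Thpok cells (single libraries 4.07% to 14.8%) and at 5.77% in Mta2-DBTBLZ cells (4.50% to 10.5%). Simulated unchanged groups gave 1.28% to 3.53% for means of 3 libraries, and no such range was drawn for single libraries.

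The lineage index, which sets the WT CD8 mean at 0 and the WT CD4 mean at 1, was 0.777 ± 0.0387 in Lz-Thpok CD4 and 0.810 ± 0.0302 in Mta2-DBTBLZ CD4 (SD, n = 3 each). Means of 3 simulated unchanged CD4 libraries, with genes chosen by the same rule, gave 0.913 (0.900 to 0.933). Genes were drawn independently there, so that range may be too narrow. The index of the retrogenic groups differed by 0.033 (exact two-sided permutation p = 0.3, n = 3 each), in a design whose smallest possible p is 0.1. CD8-enriched genes had a median log2 fold change of -0.12 in Mta2-DBTBLZ against Lz-Thpok CD4, a comparison without the WT libraries that chose the sets, although the fit's filter and spread used all 12 libraries (camera adjusted p = 0.0279, and adjusted p = 0.637 with an estimated correlation), and CD4-enriched genes one of -0.05 (camera adjusted p = 0.913). The CD8-enriched call was lost without Lz-Thpok replicate 1 (camera adjusted p = 0.133), Lz-Thpok replicate 3 (camera adjusted p = 0.639) or Mta2-DBTBLZ replicate 2 (camera adjusted p = 0.298). Among the 114 CD8-enriched genes with an absolute log2 fold change of at least 2 the median was -0.41 (camera adjusted p = 1.68e-05), and among 450 with no fold threshold it was -0.01 (camera adjusted p = 0.762).

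**Figure D3:**
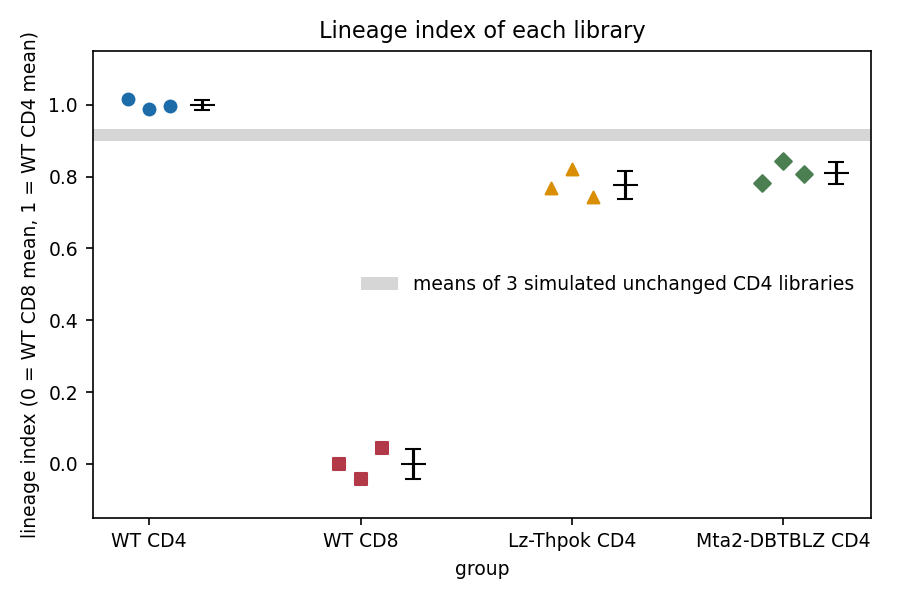
Lineage index (vertical axis, no unit; 0 is the WT CD8 mean and 1 the WT CD4 mean) of each of the 12 libraries by group, with the group mean and SD beside the points and a grey band for means of 3 simulated unchanged CD4 libraries (0.900 to 0.933). The retrogenic means, 0.777 and 0.810, lie below the band, and all 6 retrogenic libraries, at 0.744 to 0.842, lie below the range of single simulated libraries, 0.894 to 0.941. The simulation drew genes independently, so both ranges leave out variation shared across genes.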

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

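Quality weights in limma voom, the covariates, the removal of the exon-length trend and the leave-outs of the overlap were chosen only after the result was seen. Of the named genes called, 40 of 60 between WT CD4 and WT CD8 kept direction and call under every alternative, against 0 of 11 for Lz-Thpok and 0 of 23 for Mta2-DBTBLZ against WT CD4. Of the lists called, 8 of 12, 6 of 13, 0 of 10 and 0 of 7 did so, in the order of the comparisons. For the changes below the cause was not tested. Between WT CD4 and WT CD8, DESeq2 called 1542 genes, the 6 compared libraries alone 1798, limma voom with quality weights 2248 (945 without them) and the share of reads outside genes as a covariate 500, with 447 to 623 when 1 replicate was left out. For Lz-Thpok against WT CD4 the counts were 226 with DESeq2, 3 with limma voom, 77 with no low-count filter, 29 with the filter of 5 CPM, 53 with 6 libraries, 146 with quality weights in limma voom, 29 with the outside-genes covariate, 48 with the mitochondrial covariate, 29 with the length trend removed, and 0 to 17 with 1 replicate left out. For Mta2-DBTBLZ against WT CD4 they were 406 with DESeq2, 27 with limma voom, 138 with no filter, 0 with 6 libraries (edgeR), 18 with the replicate number as a block, 1 with the outside-genes covariate, and 0 to 1173 with 1 replicate left out. The labels do not say what the replicate numbers mean, and they were not used to pair samples. Correlations between libraries of the same number lay between -0.074 and 0.169. Each library correlated best with its own number in WT CD4 against WT CD8 and in Lz-Thpok against WT CD4, and 1 of 3 did in each comparison of Mta2-DBTBLZ, a hint from the data and not from the design. With the number as a block edgeR called 851, 17, 18 and 0 genes, in the order of the comparisons. Between the retrogenic groups DESeq2 called 91 genes and edgeR with no filter 5, with 0 to 109 in the leave-outs, the highest without Mta2-DBTBLZ replicate 1.

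Lists called for Lz-Thpok against WT CD4 numbered 6 with an estimated correlation and 6 with fry. For Mta2-DBTBLZ against WT CD4 they numbered 0 with an estimated correlation and 7 with fry. Between the retrogenic groups they numbered 0 with an estimated correlation, 0 with fry, 4 with the length trend removed and 2 to 8 in the leave-outs. Mitochondrially encoded genes turned to the other direction there without Lz-Thpok replicate 3 (camera adjusted p = 0.03947), with leave-outs up to 0.9322. The CD4-enriched median between the retrogenic groups was -0.031 with no fold threshold and -0.082 to 0.036 in the leave-outs. The CD8-enriched median was -0.01 with no fold threshold, -0.411 with an absolute log2 fold change of at least 2 (camera adjusted p = 1.68e-05), -0.124 with an estimated correlation, where its call ended, and -0.255 to -0.065 in the leave-outs. Genes shared by both comparisons with WT CD4 numbered 118 with DESeq2 and 0 to 41 in the leave-outs. In all, 2 values were left out because DESeq2 gave no adjusted p. Data were simulated with the real depths, 1 spread per gene for all groups and 3 libraries per group. There, 43% to 61% of 2-fold changes were called among genes of at least 8 CPM, and which of these limits the calls was not tested.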

Other observations

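The tests on WT CD8 cells, on innate-like and NK cells, on Mta2-DBTBLZ replicate 1 and on exon length were chosen only after the result was seen. Quality weights in limma voom and the share of reads outside genes as a covariate were added after the data were seen, before their own results.

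The remaining lists were not called by camera between WT CD4 and WT CD8, though several held called genes. There, helper cytokine and effector genes had 4 higher and 2 lower of 12 (5 and 2 adjusted over the list alone; median log2 fold change 0.42, camera adjusted p = 0.397), with Bcl6, a transcription factor of follicular helper cells, at 30.03 ± 2.24 against 11.9 ± 0.843 CPM (SD, n = 3). Il21, a helper cytokine, was at least 46.0-fold higher in WT CD4 than the floor of 3 counts over the WT CD8 group, where no count was found. T cell homing and adhesion genes had 4 higher and 4 lower of 23 (7 and 6 adjusted over the list alone; camera adjusted p = 0.437), with S1pr1, the receptor for thymic egress, higher in WT CD4 (1393 ± 99.0 against 906 ± 61.1 CPM) and Ccr9 lower (36.2 ± 9.01 against 575 ± 75.4 CPM). Immature and double-positive thymocyte genes had 3 higher and 3 lower of 27 (6 and 6 adjusted over the list alone; camera adjusted p = 0.124), and dissociation and heat stress genes 3 higher and 1 lower of 20 (3 and 2 adjusted over the list alone; camera adjusted p = 0.789). Gamma delta T cell markers had none of 8 (none adjusted over the list alone; camera adjusted p = 0.543) and mitochondrially encoded genes none of 11 (none adjusted over the list alone; camera adjusted p = 0.789).

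Thymic stroma markers had 1 of 5 higher in WT CD4, Pecam1, which T cells also express (1 higher adjusted over the list alone; camera adjusted p = 0.103). Dendritic cell markers had 1 of 9 lower, Ccr9 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.792), and myeloid markers none of 6 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.789). The B cell gene Ms4a1 was at most 0.566 CPM in any library, the erythroid gene Hba-a1 at most 0.279 CPM, the myeloid gene Csf1r at most 3.94 CPM, in 1 Lz-Thpok library, and the epithelial gene Epcam had group means between 4.20 and 7.70 CPM. The myeloid gene Lyz2 was at 10.9 CPM in WT CD4 replicate 1, against 0 and 0.140 CPM in WT CD4 replicates 2 and 3 and at most 0.912 CPM in the other groups. That library also had the highest mean log2 CPM of myeloid markers, 2.16 against 0.08 and 0.63, and of dendritic cell markers, 2.78 against 1.06 and 1.82 in the other WT CD4 libraries. The only tested erythroid marker, Car2, was lower in WT CD4 than in WT CD8 (20.6 ± 2.22 against 42.6 ± 2.00 CPM), a call lost without any one of these 6 libraries (edgeR adjusted p between 0.0656 and 0.126), and the only tested sex-linked gene, Xist, had no call. Against WT CD4, none of the NuRD, helper cytokine, TCR signal response, homing, myeloid, dendritic and stroma lists was called in either retrogenic group (camera adjusted p between 0.228 and 0.954 over both). Nor was the transcription factor list (camera adjusted p = 0.592 in Lz-Thpok and 0.231 in Mta2-DBTBLZ, Zbtb7b being its 1 called member), late maturation in Lz-Thpok (camera adjusted p = 0.0681, with Ly6c1 called), or, in Mta2-DBTBLZ, gamma delta (camera adjusted p = 0.259), immature thymocyte (0.0935), mitochondrially encoded (0.0809) and oxidative phosphorylation genes (0.259). Between the retrogenic groups the lists not named above, CD4 lineage, CD8 lineage and NuRD among them, were not called (camera adjusted p between 0.181 and 0.958). Median, mean and test had the same sign in each called list. The sign differed among uncalled lists, for homing and dendritic cell markers between WT CD4 and WT CD8 and in Lz-Thpok against WT CD4, where the transcription factor, helper cytokine, TCR signal and myeloid lists differed as well. In Mta2-DBTBLZ against WT CD4 it differed for myeloid and dendritic cell markers. In Mta2-DBTBLZ against Lz-Thpok it differed for the CD4 lineage, NuRD, helper cytokine, gamma delta, TCR signal, interferon, dissociation, B cell and NK cell lists.

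CD8-enriched genes were higher in both retrogenic groups than in WT CD4. Cells of the WT CD8 kind, which the CD4 gate should remove, would bring all their abundant transcripts in 1 ratio: in Lz-Thpok libraries the median share of the WT CD8 level over 66 abundant genes was 10.58%, above the highest median of 4.40% in simulated unchanged groups (the lowest library, at 2.20%, was not), while Cd8a reached at most 0.591% in any library, which argues against such cells as the whole cause there. In Mta2-DBTBLZ libraries the median was 4.073% (lowest library 0.975%), with 21 of the 66 genes at or below 0. Cd8a reached at most 0.501%, which bounds what such cells could bring if they carry Cd8a at the WT CD8 level. Of the 66 genes, 42 lay over 3 times that share. The choice of genes alone gave medians of -0.182% to 4.40% in simulated unchanged groups, with 0.761% in the middle. Those groups had 1 spread per gene, whereas real WT CD4 replicates spread least (median SD of log2 CPM 0.146, against 0.324 in Mta2-DBTBLZ). The size of this effect is therefore uncertain. Cells of the WT CD8 kind could bring at most 0.501% under that condition, against the median of 4.073%, which argues against them as its whole cause. The median does not separate a change within CD4 cells from the choice of genes. Another measure kept each WT CD4 library in turn out of choosing the set and used it as the control. The Mta2-DBTBLZ log2 medians were then 0.34, 0.232 and 0.368 over all set genes. They argue against the choice of genes as the whole cause of the rise, though each rests on 1 control library. A contribution of innate-like or NK cells, which the CD44-low, TCRβ-high gate should reduce, remained open. Their 13 tested markers outside the set had median log2 fold changes of 0.1676 in Lz-Thpok and 0.2964 in Mta2-DBTBLZ, 8 positive in each. The set had 0.528 and 0.392. Itga2 alone gave both marker medians (1.83 and 2.00 against 1.63 CPM in WT CD4). No marker was called (lowest edgeR adjusted p = 0.102 and 0.185), and all but Ifngr1 lay at or below 2.245 CPM in WT CD4. Gzma (14.2 and 5.32 against 0.450 CPM) and Klra3 (1.27 and 1.04 against 0.268 CPM) were among the higher ones. Lower in both groups were Zbtb16 (0.655 and 0.502 against 1.27 CPM), Eomes (1.68 and 0.933 against 2.245 CPM), Cxcr3 and Xcl1. Markers at such low levels cannot decide the question. Transplantation and transduction cannot be told apart from the constructs, since 0 libraries of wild-type marrow taken through the same steps exist in the series, and a construct effect remains open as untested.

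No gene was called by edgeR between the retrogenic groups, with 1002 genes at an unadjusted p under 0.05, 91 called by DESeq2 and 0 by limma voom. The share of reads outside genes as a covariate left 0 calls, with 517 genes at an unadjusted p under 0.05. A quality weight per library in limma voom left 0, with 748 such genes. That share differed between the groups (means 8.22% in Lz-Thpok and 6.12% in Mta2-DBTBLZ), and weights do not remove the spread between replicates. Neither refit can therefore decide whether quality or spread kept the count at 0. Removal of the exon-length trend left 0 calls, with 1058 such genes, which argues against that trend as what kept the count at 0. Without Mta2-DBTBLZ replicate 1 the count was 109, and it was 0 without each of the other 5 libraries. That leave-out kept Mta2-DBTBLZ replicates 2 and 3, which stood apart from the other CD4 libraries. In a principal component analysis of log2 CPM they lay at -62.75 and -78.29 on component 2. The other CD4 libraries lay between -1.81 and 50.4 there, replicate 1 at 25.43. The distance of replicate 1 from these 2 libraries may account for the count of 0. The 109 calls cannot be told apart from library quality. Genes called lower in Mta2-DBTBLZ in that leave-out had a median exon length of 6241 bases and those higher 2774, against 3688.5 over tested genes. With the length trend removed 77 genes were called, 64 of them shared. Lists called between these groups differed in this respect: the oxidative phosphorylation median went from 0.19 (quartiles 0.166 to 0.274) to 0.04 (quartiles -0.013 to 0.12), as a length trend would give, whereas the proliferation median went from -0.50 to -0.595, which argues against length as its cause.

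Other splits of the 6 libraries of each comparison were fitted in the same way, and 10 splits are too few for a share under 0.05. For WT CD4 against WT CD8 the real split called 816 genes and the highest other split 0, for Lz-Thpok against WT CD4 16 and 0, and for Mta2-DBTBLZ against WT CD4 54 and 0, so 1 of 10 splits called as many in each. For Mta2-DBTBLZ against Lz-Thpok all 10 splits called at least the real count of 0, and the highest other split called 378. That split set Lz-Thpok replicate 2 with Mta2-DBTBLZ replicates 2 and 3, the 3 of these 6 libraries with the lowest mitochondrial shares and the fewest genes with a count, and points to a structure among the samples that does not follow the groups. Of its 378 calls, 19 were among the 109 genes called without Mta2-DBTBLZ replicate 1, so most of the 109 were not called by that split. Its genes lower on the side of 2 Mta2-DBTBLZ libraries had a median exon length of 5969 bases, and those higher 3298. Whether quality gave the 109 calls stays open.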
